A study of Mus musculus with 9 samples.

How the data were processed

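Quadriceps femoris muscle of 9 female mice was profiled, 1 array per sample, in 3 groups of 3. Per the labels' protocols, total RNA was copied with an oligo(dT) primer, labelled with biotin and hybridised to Affymetrix arrays, on which a gene is read by 1 or more sets of short probes near the 3' end of its transcript. The deposited log2 values of the authors came from GCRMA, per the submitters' processing notes. GCRMA corrects background with the probes' base composition, normalizes arrays to one another and summarises each probe set; its version and settings are not given in the sources used here. The table held 45101 probe sets and 9 arrays, and every column of it was used. GCRMA gives dim probe sets nearly equal values, which narrows their spread, and it makes the arrays' overall distributions alike, so a shift common to all genes would not be seen. Per array the median lay between 3.41 and 3.45 on the log2 scale, and between 17391 and 17735 probe sets lay above a log2 value of 5. The precision of every comparison is limited by the number of arrays, 3 per group. No scan date or other batch was given in the sources used here.

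Probe sets were named from the platform annotation. Of the 45101 probe sets, 34958 named 1 gene, 932 named several and 9211 named none in that table; symbols were compared with a table of assembly GRCm38.p6 through the gene identifier, and 0 needed an update. The 64 control probe sets and those naming several genes or none were left out of the comparisons. A probe set was kept where its log2 value was above 5 in at least 3 arrays, which left 16048, and for each gene the probe set with the highest mean over the 9 arrays was taken, which left 9697 genes; 3988 of these had more than 1 passing probe set. Among the genes called changed that had several, a probe set of opposite sign was found for 0 of 50 genes in early against control, for 1 of 7 in late against control and for 110 of 493 in early against late. At an unadjusted p under 0.05 the opposite sign remained for 0, 1 and 21 of these genes.

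Groups were taken from the sample labels. One model of 3 group means was fitted per gene to all 9 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that the groups shared 1 estimate of the spread, with 6 residual and 2.84 prior degrees of freedom; the median residual SD of a gene was 0.26 on the log2 scale. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. All adjusted p values given for genes are from this limma fit. An exact test of 3 against 3 arrays cannot go below p = 0.1 and was not used. The labels number the animals within groups but do not say whether replicates share anything else. Sample titles also hold a longer number, consecutive for replicate 3 of the early and late groups, whose meaning is not given. P values measure the spread between these samples.

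For 31 gene lists fixed before the data were examined, 28 had at least 3 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison. Camera with an estimated correlation, and fry, were run beside it. Camera asks whether a list moved relative to the other genes; fry asks whether its members moved, on balance, one way. Members were also adjusted over the list alone. The genes named were fixed by a rule before the data were examined: H2-K1 and the other classical class I genes; the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap; and, from each list, up to 4 members with the smallest p in that comparison. Genes named outside the rule are said to be so.

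The early and late groups were compared with the same 3 controls, so 100 simulations of unchanged groups against those controls were made for the correlation of the changes. Whether replicate numbers pair the samples was checked from the correlation, across genes, of the deviations of same-numbered arrays from their group means. For early and late arrays it was 0.168, 0.201 and 0.16, all above 0.1, so these numbers were treated as pairing the early and late arrays, although no label says what they share; the fit reported has no block, and the block was run beside it. For early and control arrays it was 0.35, 0.11 and -0.0391, and for late and control arrays 0.0847, -0.165 and -0.11, so those were not. The block nevertheless held the control arrays too, by their replicate numbers.

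The fit was tested on simulated data with the genes' control means and 1 pooled spread per gene for all groups. In these data 200 of 9697 genes were changed in the early against control comparison. It recovered 52.8% of the genes changed by 1 on the log2 scale, 89% at 2, 97.4% at 3 and 98.2% at 4, and 5.16% of the calls were false. A simulated rise of the proteasome list by 1 was found in 100% of 20 simulations. The simulated genes varied independently and with equal spread in every group. Real genes within lists were correlated (estimated at 0.915 for MHC class II), and real control arrays were more alike than induced ones. These rates may therefore not hold for the real calls. The alternatives planned were no filter, a filter at 7, a trended and robust eBayes, median centring, a further quantile normalization, the mean of a gene's probe sets, no probe sets with the suffix for shared probes, every probe set, a fit of only the groups compared, array weights, the replicate number as a block, stricter thresholds and leaving out each array. In addition, 7 gene sets were picked by symbol and tested after the results had been seen, with adjustment over the 7. No genome build was given with the values, and no coordinates are reported.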

Results

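The data are expression values of quadriceps femoris, a thigh muscle, from 9 female mice of a C57Bl/6 line carrying a transgene for a self MHC class I protein, the molecule that displays peptides of a cell's own proteins on its surface. The transgene is switched on in skeletal muscle when doxycycline, an antibiotic that represses it, is withdrawn. Early mice (n = 3) were taken off doxycycline at 21 days of age and killed at 35 days, after 2 weeks of expression. Late mice (n = 3) stayed on the drug until 35 days and were killed at 50 days per their sample labels. Control mice (n = 3) were kept on doxycycline and killed at 35 days. The protocol calls them littermates with a single transgene, while the strain label is the same for all 3 groups. The labels therefore leave open whether controls differed in genotype. Early and control mice had the same age, but differed in drug, and in genotype if the protocol holds, as well as in transgene expression. Late mice were also older than the controls, so the effects of age and of induction cannot be told apart in that comparison. Values are log2 expression, given as mean ± SD (n = 3) or as log2 difference ± SE.

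H2-K1, a classical MHC class I gene, was higher in both induced groups. It stood at 10.52 ± 0.34 in controls, 14.66 ± 0.03 in early and 13.87 ± 0.66 in late muscle, a rise of 17.7-fold in early mice (4.14 ± 0.31, adjusted p = 0.00115) and of 10.2-fold in late mice (3.35 ± 0.31, adjusted p = 0.00446). The difference of 0.79 ± 0.31 between early and late mice did not pass the test (adjusted p = 0.112), on a probe set near the top of the scale. H2-D1, the other classical class I gene tested, differed by 0.71 ± 0.36 in early mice (adjusted p = 0.313) and by 0.28 ± 0.36 in late mice, and neither passed. The probe sets of these genes did not give 1 size. For H2-K1 the early difference was 5.10, 7.29 and 0.61 on the other probe sets, and for H2-D1 it was as high as 3.25 on a probe set that was dim in controls. On those H2-K1 probe sets, in the same order, late mice differed from controls by 4.06, 3.997 and 0.47. The middle probe set had a control mean of 4.64, under the filter's floor of 5, and counted from the floor its differences were 6.93 and 3.64. Early differed from late mice by 1.04, 3.29 and 0.14 (adjusted p = 0.205, 0.103 and 0.781 over all probe sets). The size of the early and late difference in H2-K1 is therefore not settled. The class I genes are near-identical in sequence, so their probe sets can read one another's transcripts, and the brightest lie near the top of the scale.

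**Figure D1:**
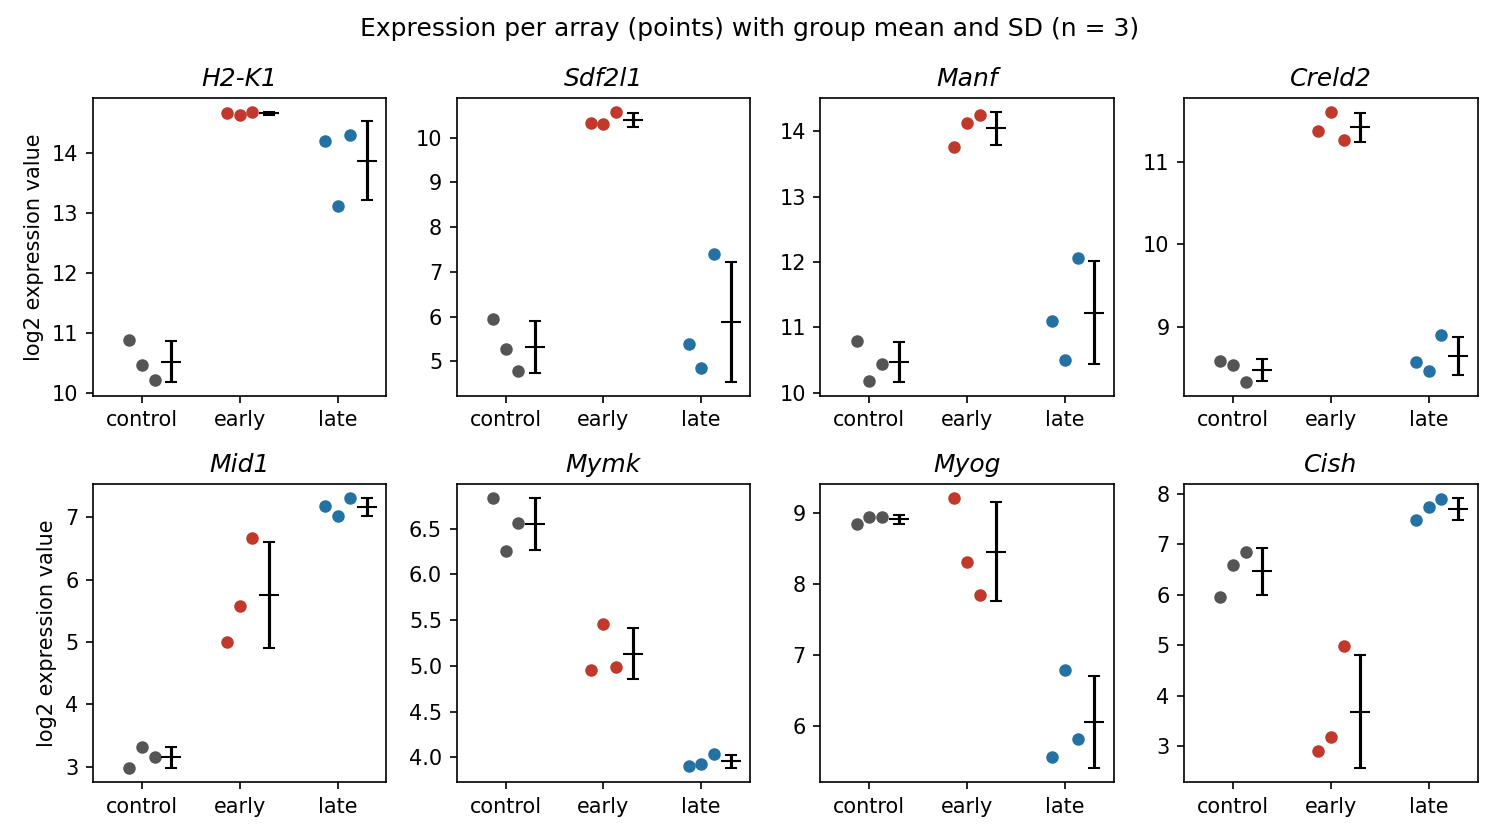
Log2 expression of 8 genes in each of the 9 arrays (points; vertical axes differ between panels and do not start at 0), with the group mean and SD (black, n = 3). H2-K1 was higher in every early and late array than in any control array, whereas Sdf2l1, Manf and Creld2 were raised in the early arrays (mean Manf 14.05, against 10.47 in controls and 11.22 in late arrays).

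Early induction was compared with controls of the same age to ask what 2 weeks of class I expression does in young muscle. Of the 10 genes with the largest log2 rises in early mice, 7 act in the endoplasmic reticulum (ER), where proteins are folded. Sdf2l1, part of an ER chaperone complex, rose 33.6-fold (5.07 ± 0.58, adjusted p = 0.00759). Derl3, which acts in the degradation of misfolded ER proteins, rose by 4.07 ± 0.37, and Manf, a secreted protein induced by ER stress, rose 12-fold (3.58 ± 0.36). Hyou1, an ER chaperone, rose by 2.98 ± 0.36, Creld2, also induced by ER stress, by 2.93 ± 0.16, Fkbp11, a proline isomerase, by 2.68 ± 0.30, and Pdia6, a disulfide isomerase, by 2.56 ± 0.30. The remaining genes of the 10 largest rises, beside H2-K1, were Tnfrsf12a, the receptor for the cytokine TWEAK (2.90 ± 0.44), and Mid1, a ubiquitin ligase bound to microtubules (2.60 ± 0.36). The control means of Derl3 (2.23) and Mid1 (3.15) lay under the filter's floor of 5, so their sizes and ranks are uncertain. Counted from the floor they rose by at least 1.30 and 0.75.

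Cish, a suppressor of cytokine signalling induced by STAT5, fell (-2.78 ± 0.49, adjusted p = 0.0388). Pbk, a mitotic kinase (-1.89), Acvr1b, an activin receptor (-1.52), Mymk, which fuses myoblasts (-1.42), and Ky, a muscle structural gene (-1.38), also fell. So did Tmem25 (-1.49), Fcor (-1.40), Mal (-1.39) and the transcripts 6430571L13Rik (-1.94) and 9630013D21Rik (-1.75). The early means of Cish, Pbk and 9630013D21Rik lay under the floor, and counted from it their differences were -1.46, -1.25 and -0.75. In all, 115 of 9697 genes were called changed, 90 higher and 25 lower, and 94 of these changed at least 2-fold; 1797 genes had an unadjusted p under 0.05, where chance gives 485. The groups did not overlap for 23.6% of genes, against 10% by chance. The count was 56 with no filter, 61 when only early and control arrays were fitted and 3335 with array weights. It was 37, 6 and 13 without control 1, 2 or 3, 62 and 22 without early 1 or 2, 67 without late 2, and 1756 without early 3.

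In the list of ER stress and unfolded protein response genes, 16 of 33 members tested rose in early mice, 0 fell and 17 did not pass, with a median of 1.14 (2.20-fold), and 22 rose when adjusted over the list alone. Dnajb11, a co-chaperone, rose by 2.04 ± 0.22 and Pdia4, a disulfide isomerase, by 2.24 ± 0.21. The list was higher by camera (adjusted p = 8.36e-20; adjusted p = 0.0525 with an estimated correlation) and by fry (adjusted p = 0.000417). Its median was 0.997, 1.38 and 1.27 over the control mean in early 1, 2 and 3, against 0.30, 0.07 and 0.47 in late 1, 2 and 3. The number of members that rose fell to 2 without control 2.

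Several other lists were higher in early mice by camera with few or no members called. All 6 MHC class II genes, which present antigen on immune cells, had positive values. Of these 0 passed over all genes and 5 rose adjusted over the list alone, for example H2-Eb1 (2.01 ± 0.68) and Cd74 (1.62 ± 0.51). The list's median was 1.63 (adjusted p = 0.000771; adjusted p = 0.507 with an estimated correlation). Of 24 macrophage genes 0 passed and 22 had positive values (median 0.46, adjusted p = 0.000771; adjusted p = 0.507 with an estimated correlation). Lgals3, a lectin of activated macrophages, differed by 2.98 ± 1.19. Of 14 denervation and neuromuscular junction genes 0 passed (median 0.72, adjusted p = 0.00632; adjusted p = 0.507 with an estimated correlation), with Ncam1, an adhesion molecule, at 2.17 ± 0.70 and Ache, acetylcholinesterase, at 1.86 ± 0.63. Of 19 heat shock and oxidative stress genes 0 passed, and 1 rose adjusted over the list alone (median 0.61, adjusted p = 0.000325; adjusted p = 0.507 with an estimated correlation). Hspa1a differed by 2.27 ± 0.69. Of 31 proteasome subunits 0 passed (median 0.18, adjusted p = 0.00156; adjusted p = 0.507 with an estimated correlation). In the atrophy and autophagy list of 24, 1 gene rose, Fbxo32, which encodes the muscle ubiquitin ligase atrogin (1.88 ± 0.35, adjusted p = 0.0446), and Trim63, another such ligase, differed by 0.69 ± 0.25 (list median 0.20, adjusted p = 0.045; adjusted p = 0.507 with an estimated correlation).

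These lists were not raised alike in the 3 early arrays. The macrophage median was 0.98, 0.69 and -0.22 over the control mean in early 1, 2 and 3, the denervation median 1.12, 1.04 and -0.35, the heat shock median 1.02, 0.79 and -0.03, and the MHC class II median 2.14, 2.27 and 0.47. The median of slow fibre genes, 0 of 13 of which passed, was 2.36, 0.26 and -1.65 in the same arrays. The number of members called also depended on single arrays. Leaving out 1 array gave 0 to 10 higher macrophage genes, 0 to 9 denervation genes and 0 to 9 heat shock genes. It gave 0 to 8 atrophy genes, 0 to 6 MHC class II genes and 0 to 5 proteasome genes. Without early 1 the denervation list was not called (adjusted p = 0.1), and without control 1 the atrophy list was not (adjusted p = 0.201). Fbxo32 was called in that list only with all arrays or without early 3; its adjusted p was 0.167 without control 1 and 0.16 without early 2. Proteasome medians were 0.33, 0.23 and -0.01 and atrophy medians 0.42, 0.20 and 0.01 in early 1, 2 and 3.

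Lower lists in early mice held markers of other cell types and of growth, and 0 of their members passed over all genes. They were the cell cycle (19 genes, median -0.74; Mcm5, a replication helicase subunit, -1.02 ± 0.28; adjusted p = 4.78e-05), adipocytes (16 genes, median -1.29; Adipoq, the hormone adiponectin, -1.47 ± 0.39; adjusted p = 1.79e-05), the imprinted postnatal growth network (13 genes, median -0.62; Igf1 -1.26 ± 0.42; adjusted p = 0.00905) and the circadian clock (13 genes, median -0.58; Dbp -2.46 ± 0.78; adjusted p = 0.0385). With an estimated correlation these 4 had adjusted p = 0.507, 0.507, 0.443 and 0.507 in that order. Endothelial cells (18 genes, median -0.28; adjusted p = 0.00862), smooth muscle and pericytes (11 genes, median -0.32; Acta2 -0.72 ± 0.17; adjusted p = 0.0177) and Schwann cells and nerve (7 genes, median -0.42; Mbp, a myelin protein, -0.96 ± 0.22; adjusted p = 0.0177) were also lower, with adjusted p = 0.507, 0.443 and 0.443 with an estimated correlation. By fry, smooth muscle (adjusted p = 0.0196) and Schwann cells (adjusted p = 0.0438) were lower too. Metabolic lists were lower by small amounts: oxidative phosphorylation (40 genes, median -0.13; adjusted p = 0.0114), the citrate cycle and fatty acid oxidation (34 genes, median -0.22; adjusted p = 0.00396), glycolysis and glycogen (20 genes, median -0.28; adjusted p = 0.0211) and fast fibre genes (19 genes, median -0.13; adjusted p = 0.0211). With an estimated correlation the fast fibre list had adjusted p = 0.558 and the other 3 had adjusted p = 0.507. Leaving out 1 array ended the camera call of the imprinted, smooth muscle and Schwann lists (adjusted p = 0.0905, 0.123 and 0.168 without early 3), of the circadian and oxidative phosphorylation lists (0.086 and 0.0599 without early 2), and of the glycolysis and fast fibre lists (0.1 and 0.108 without early 1). In early 1, 2 and 3 the glycolysis medians were -0.47, -0.30 and 0.04 and the fast fibre medians -0.28, -0.16 and -0.01.

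Of the lists not called in early mice, the MHC class I pathway had 1 of 13 members higher, H2-K1, and a median of 0.14. The medians were -0.07 for type I interferon response, 0.27 for interferon gamma response, 0.06 for inflammatory cytokines, -0.22 for complement, -0.45 for neutrophils and mast cells, -0.18 for extracellular matrix, 0.02 for slow fibre genes and 0.16 for apoptosis. In the regeneration list of 22 genes Mymk fell and the median was -0.01; Ankrd1, a stress-responsive muscle gene, differed by 3.54 ± 0.97 without passing. The median and mean differed in sign for the regeneration, type I interferon and slow fibre lists. T and NK cells (2 genes measured above the floor, Cd28 and Thy1), B and plasma cells (2, Derl3 and Ighm) and erythroid cells (1, Alas2) were too few to test as lists; Cd28 differed by -1.01 ± 0.51, Thy1 by -0.56 ± 0.54, Ighm by -2.85 ± 1.37 and Alas2 by -1.06 ± 0.55, none of which passed.

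**Figure D2:**
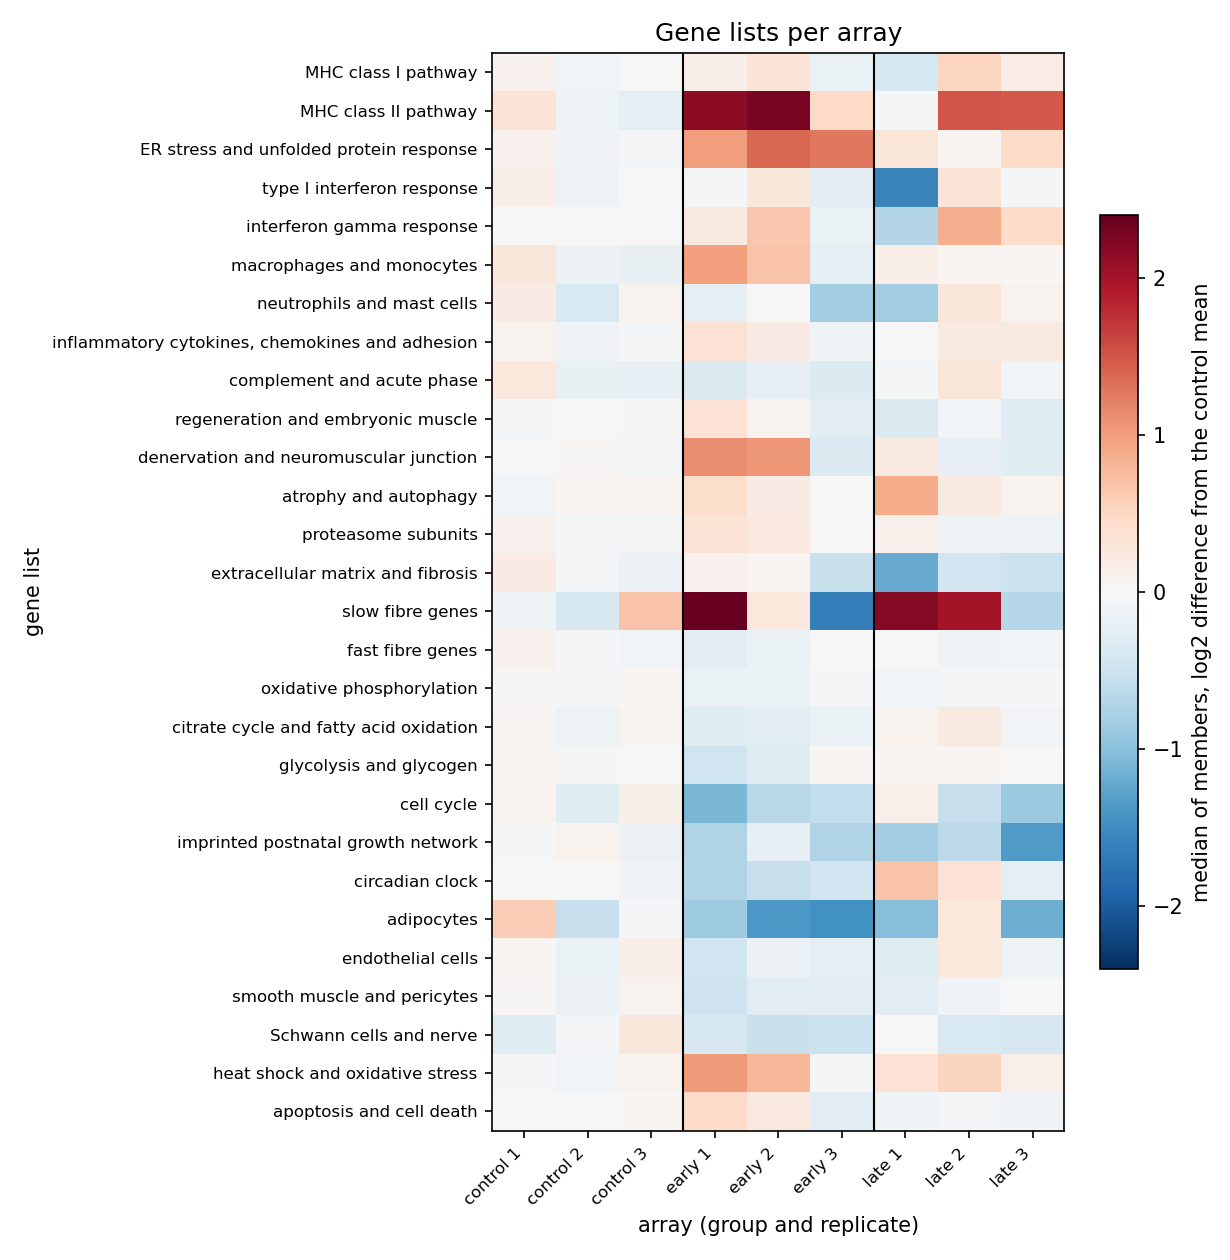
Median of the members of each of 28 gene lists in each array, as log2 difference from the control mean (red higher, blue lower). The ER stress list was raised in all 3 early arrays (0.997 to 1.38), while the macrophage, denervation and heat shock lists were raised in early 1 and 2 and lay at or below 0 in early 3.

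Late induction was set against the same controls to ask what class I expression does in older muscle. Late mice were older than the controls, so each value below holds age as well. In late mice Myog, a transcription factor of muscle differentiation, fell by 2.86 ± 0.39 (adjusted p = 0.0359) and Mymk by 2.60 ± 0.19 (adjusted p = 0.0016). Kcne1l, a potassium channel subunit, fell by 3.03 ± 0.32 and Cthrc1, a secreted matrix protein, by 2.67 ± 0.25. Pbk (-2.26), Nrk, a kinase (-2.24), Rab4b (-1.61), Trim2 (-1.31), Ift27 (-1.07) and Col16a1, a collagen chain (-1.03), fell as well. Mid1 (4.01 ± 0.36, adjusted p = 0.00446), H2-K1 and the transcript 2610507I01Rik (2.90 ± 0.20) rose. Prelp, a matrix proteoglycan, rose by 1.65, Mmrn1 by 1.26, Tnfrsf19 by 1.21, Atmin by 1.07, Abcb4, a phospholipid transporter, by 1.04 and Uaca by 0.99. Group means under the floor leave the sizes of some of these uncertain: counted from the floor the differences were 2.17 for Mid1, 0.41 for 2610507I01Rik, -1.59 for Kcne1l, -1.55 for Mymk, -1.25 for Pbk and -0.94 for Nrk.

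In late mice 20 of 9697 genes were called, 9 higher and 11 lower, and 1673 had an unadjusted p under 0.05, where chance gives 485. The groups did not overlap for 31% of genes, against 10% by chance. With arrays centred on their medians 8 genes were higher and 18 lower. The count was 13 without shared-probe sets, 12 when only late and control arrays were fitted and 1037 with array weights. It was 5, 5 and 6 without control 1, 2 or 3, 6 without early 2, 59 without early 3, and 9 and 6 without late 1 or 2.

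Growth and matrix lists were lower in late mice. Of 13 genes of the imprinted postnatal growth network, 0 passed over all genes and 10 fell adjusted over the list alone, with a median of -1.09; Cdkn1c, a cell cycle inhibitor, differed by -1.71 ± 0.26, Igf2, a growth factor, by -1.47 ± 0.38 and the non-coding Rian by -2.22 ± 0.51. The list was lower by camera (adjusted p = 3.45e-07; adjusted p = 0.11 with an estimated correlation) and by fry (adjusted p = 0.0137). Its medians were -0.83, -0.64 and -1.37 over the control mean in late 1, 2 and 3. Of 30 extracellular matrix genes 0 passed and 6 fell adjusted over the list alone (median -0.76, adjusted p = 1.33e-08; adjusted p = 0.71 with an estimated correlation), for example Col5a1 (-1.30 ± 0.28), Eln, elastin (-1.73 ± 0.42), and Col1a1 (-0.85 ± 0.18). Of 19 cell cycle genes 0 passed and 2 fell adjusted over the list alone (median -0.43, adjusted p = 0.000298; adjusted p = 0.71 with an estimated correlation): Mcm5 at -1.36 ± 0.28 and Stmn1, which binds tubulin, at -1.47 ± 0.35. The cell cycle medians were 0.12, -0.55 and -0.88 in late 1, 2 and 3. Late 1 thus had no fall. In the regeneration list 2 of 22 genes fell, Myog and Mymk, and the list itself was not called (adjusted p = 0.0725). In the denervation list, which shares Myog, 1 of 14 fell.

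The other 4 lists called in late mice each lost the call on leaving out 1 array. Adipocyte genes (0 of 16 passed, median -0.75, adjusted p = 0.0108; adjusted p = 0.916 with an estimated correlation) lay at -1.03, 0.26 and -1.18 in late 1, 2 and 3, and were not called without late 3 (adjusted p = 0.238). Type I interferon genes (0 of 20 passed, median -0.28, adjusted p = 0.0282; adjusted p = 0.916 with an estimated correlation) lay at -1.58 in late 1 against 0.32 and -0.03 in late 2 and 3, and were not called without late 1 (adjusted p = 0.651). The ER stress list was higher with 0 of 33 members called (median 0.27, adjusted p = 0.0204; adjusted p = 0.71 with an estimated correlation) and was not called without late 3 (adjusted p = 0.248). Atf6, a sensor of ER stress, differed by 0.81 ± 0.18 and rose adjusted over the list alone. Atrophy genes were higher with 0 of 24 called (median 0.36, adjusted p = 0.019; adjusted p = 0.71 with an estimated correlation), with Fbxo32 at 1.16 ± 0.35 and Foxo1 at 1.06 ± 0.42, and were not called without late 1 (adjusted p = 0.134).

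The other lists were not called in late mice. MHC class II genes had a median of 0.95, with array medians of -0.04, 1.51 and 1.47, and slow fibre genes a median of 1.63, with array medians of 2.21, 1.99 and -0.69. Medians were -0.02 for the MHC class I pathway, in which H2-K1 rose, 0.20 for interferon gamma response, 0.08 for macrophages, -0.12 for neutrophils and mast cells, 0.02 for cytokines, -0.09 for complement, -0.06 for denervation, 0.01 for the proteasome, -0.02 for fast fibre genes, -0.05 for oxidative phosphorylation, 0.09 for the citrate cycle and fatty acid oxidation, 0.04 for glycolysis, 0.28 for the clock, -0.00128 for endothelial cells, -0.22 for smooth muscle, -0.41 for Schwann cells, 0.24 for heat shock and -0.08 for apoptosis. The median and mean differed in sign for the MHC class I, fast fibre, neutrophil and proteasome lists.

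Early and late mice were compared directly, which tests whether their differences from the shared controls were unequal. Age at induction and age at death differ together in this contrast. Of the 10 largest rises in early against late mice, 5 were in ER genes. Sdf2l1 was 23-fold higher in early mice (4.52 ± 0.58, adjusted p = 0.00627), and Derl3 (4.06 ± 0.37) and Fkbp11 (3.31 ± 0.30) were higher as well. Manf was higher by 2.83 and Creld2 by 2.77, as were Tnfrsf12a (3.11), the transcript A930003A15Rik (4.02), Tmem158 (2.98), Emilin1, a matrix glycoprotein (2.97), and Hbegf, a growth factor (2.74). Cish was lower in early mice (-4.02 ± 0.49, adjusted p = 0.00578). Mylk4, a myosin light chain kinase, differed by -3.24, Tmem100 by -2.79, Slc16a10, an amino acid transporter, by -2.74, Ctxn3 by -2.68, Adhfe1 by -2.67, Hlf by -2.64, Crhr2 by -2.52, Ccn2 by -2.50 and Fzd4, a Wnt receptor, by -2.48, all of which passed. Counted from the floor, under which 1 group mean of each lay, the differences were 1.30 for Derl3, 2.77 for Fkbp11, 2.21 for Emilin1, -2.71 for Cish and -2.31 for Hlf. With the replicate number as a block Hlf (adjusted p = 0.0534), Ctxn3 (0.0585) and Ccn2 (0.0662) did not pass.

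Between early and late mice 1119 of 9697 genes were called, 515 higher in early and 604 lower, of which 501 differed at least 2-fold; 3313 had an unadjusted p under 0.05, where chance gives 485, and the groups did not overlap for 32.1% of genes, against 10% by chance. With arrays centred on their medians 631 were higher and 489 lower. The count was 38 when only early and late arrays were fitted, 584 with no filter and 3534 with array weights. The main fit shares 1 spread estimate with the controls. Control arrays were more alike (mean correlation with the rest of their group 0.986 to 0.990) than early (0.946 to 0.968) or late arrays (0.961 to 0.973). The p values of this contrast may therefore be too small, and the main count and named calls too generous. With every probe set kept, 1794 of 17953 probe sets passed, which named 1384 genes. The main count was 499, 310 and 395 without control 1, 2 or 3, 214, 160 and 2959 without early 1, 2 or 3, and 294, 143 and 727 without late 1, 2 or 3.

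Of 33 ER stress genes 17 were higher in early than late mice and 0 lower (median 0.86, adjusted p = 5.55e-09; adjusted p = 0.341 with an estimated correlation; fry adjusted p = 0.00166), including Pdia4 (2.36 ± 0.21), Pdia6 (2.47 ± 0.30) and Dnajb11 (1.75 ± 0.22). The number higher was 8 without early 2. In the denervation list 2 of 14 were higher, Ache (2.35 ± 0.63) and Myog (2.41 ± 0.39) (median 0.85, adjusted p = 0.00605; adjusted p = 0.776 with an estimated correlation). In the macrophage list 1 of 24 was higher, the complement gene C1qa (1.70 ± 0.46; median 0.41, adjusted p = 0.0111; adjusted p = 0.776 with an estimated correlation), and in the proteasome list 1 of 31, Psmd11 (0.78 ± 0.19; median 0.14, adjusted p = 0.0218; adjusted p = 0.776 with an estimated correlation). The extracellular matrix list was higher in early mice (30 genes, median 0.65, adjusted p = 0.00238), although its 1 called member, Ccn2, a growth factor of connective tissue, was lower. The list median over the control mean was 0.10, 0.05 and -0.54 in early 1, 2 and 3 and -1.21, -0.46 and -0.51 in late 1, 2 and 3, so early 3 lay below late 2 and 3. The imprinted growth network (0 of 13 called, median 0.56, adjusted p = 0.0372) and type I interferon (0 of 20 called, median 0.63, adjusted p = 0.0472) were higher too, and all 3 had adjusted p = 0.776 with an estimated correlation. Without 1 array the camera call ended for type I interferon (adjusted p = 0.962 without late 1), imprinted growth (0.114 without late 3), macrophages (0.112 without early 1), denervation (0.0516 without early 1) and the proteasome (0.0978 without late 3). Without control 1 the macrophage and proteasome lists had 0 members called. The highest counts of higher members on leaving out 1 array were 12 for macrophages and 8 for the proteasome. They were 11 for denervation and 12 for extracellular matrix. With the replicate number as a block type I interferon (adjusted p = 0.0771), Ache (0.0533), C1qa (0.0574) and Ccn2 (0.0662) did not pass.

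In the circadian list 5 of 13 genes were lower in early than late mice, including Hlf and the clock repressors Per3 (-1.56 ± 0.38), Cry2 (-1.42 ± 0.38) and Nr1d2 (-0.97 ± 0.24) (median -0.87, adjusted p = 0.0068; adjusted p = 0.776 with an estimated correlation; fry adjusted p = 0.0489). In the citrate cycle and fatty acid oxidation list 3 of 34 were lower, among them Ppargc1a, a regulator of mitochondrial genes (-1.54 ± 0.29), and Etfdh (-0.86 ± 0.22) (median -0.28, adjusted p = 0.00238; adjusted p = 0.776 with an estimated correlation). In the glycolysis list Phka1, a subunit of the kinase that starts glycogen breakdown, was lower (-0.91 ± 0.20; median -0.18, adjusted p = 0.0291; adjusted p = 0.776 with an estimated correlation), and that call ended without early 2 (adjusted p = 0.0775). Fast fibre genes had 3 of 19 lower, Mylk2 (-1.19 ± 0.20), Ryr1 (-0.70 ± 0.16) and Cacna1s (-0.79 ± 0.18), of which Ryr1 and Cacna1s encode calcium channels, in a list that was not called (adjusted p = 0.138). Several of these genes lay near the threshold: with the replicate number as a block Hlf (adjusted p = 0.0534), Per3 (0.0581), Cry2 (0.0626), Nr1d2 (0.0563), Tef (0.0531), Etfdh (0.0531) and Ryr1 (0.0516) did not pass, which left 0 of the clock genes called.

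Lists without a camera call in this contrast still held single called genes. Of the cytokine list Relb, an NF-kappaB subunit, was higher in early mice (2.67 ± 0.54; 2.396 counted from the floor) and Il15 (-1.39 ± 0.34) and Vcam1 (-0.97 ± 0.25) were lower. Mymk (1.18 ± 0.19) and Myog were higher in the regeneration list, Hspb1, a small heat shock protein, was higher (1.58 ± 0.38), and Myh11, smooth muscle myosin, was lower (-1.28 ± 0.15) in a smooth muscle list that was lower by fry (adjusted p = 0.0489). Lower in early mice were also Ulk1 (-0.87 ± 0.20) and Fbxo31 (-1.45 ± 0.40) of the atrophy list, Lyve1 (-1.13 ± 0.28) and Flt4 (-0.83 ± 0.23) of the endothelial list, Fas (-0.80 ± 0.16), Serping1 (-0.56 ± 0.13), Sdha (-0.78 ± 0.20) and Mbp (-0.80 ± 0.22). With the replicate number as a block Vcam1 (adjusted p = 0.0624), Ulk1 (0.0521), Fbxo31 (0.0564), Lyve1 (0.0555), Flt4 (0.0641), Sdha (0.0575) and Mbp (0.0731) did not pass. Medians of lists with 0 called members were 0.15 for the MHC class I pathway, 0.72 for MHC class II, -0.01 for interferon gamma, -0.14 for neutrophils and mast cells, -0.80 for slow fibre genes, -0.06 for the cell cycle and -0.48 for adipocytes. The median and mean differed in sign for the interferon gamma and atrophy lists.

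Few genes were called in both comparisons with the controls. H2-K1, Mid1 and 2610507I01Rik were called higher in both and Mymk and Pbk lower in both, 3 and 2 genes where independent lists of these sizes would share 0.0835 and 0.0284 and simulated unchanged groups shared 0. The control and early means of 2610507I01Rik, 2.51 and 4.91, both lay under the floor, so its early rise is not secure, and H2-K1 and Mid1 are left as shared rises. The simulated groups hold no effects and so almost no calls, and the value for independent lists leaves out the shared controls, so neither shows whether the overlap is a shared effect. Mid1 rose by 2.60 in early and 4.01 in late mice and differed between them by -1.42 ± 0.36 (adjusted p = 0.0408). Across genes, which are not independent replicates, the early and late log2 differences had Pearson r = 0.166 and Spearman rho = 0.051, and 49.9% of genes had the same sign. Simulated unchanged groups set against shared simulated controls gave a mean r of 0.501 (0.415 to 0.551) and 66.7% of the same sign. The covariance was 0.0397 against a simulated 0.0488. The simulation gave all groups the same spread, which sets its r in advance. The real control arrays were more alike than those of the induced groups, so the simulated values may be too high here. They do not show whether effects were shared beyond the controls. The 3 controls were too few to divide, so part of the sharing may come from them. Mice of both induced groups also differed from controls in drug and, by the protocol, in genotype.

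**Figure D3:**
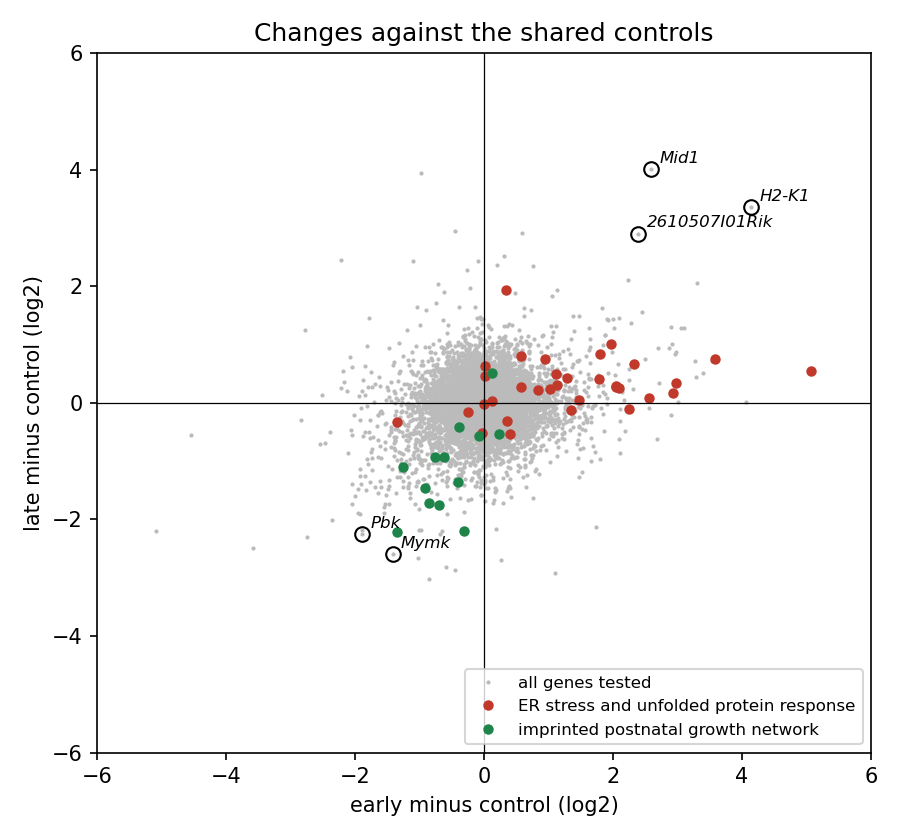
Log2 difference from the shared controls in early mice (horizontal axis) and late mice (vertical axis) for 9697 genes (grey), with the ER stress list in red and the imprinted growth network in green; circled genes were called in both. ER stress genes spread to the right (median 1.14) and little upward (0.27). Genes of the imprinted growth list lie mostly below 0 on the vertical axis (median -1.09).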

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

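The splits of the arrays were planned; the tests of label exchange, transgene mRNA, single arrays, plasma cells and age were chosen after the results were seen, that of plasma cells after the values of its genes had been viewed. No group had enough arrays for a test of outlying samples.

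A difference between the early and late groups, by the direct contrast at an adjusted p under 0.05, was found for 28 genes with the largest changes against controls. Early minus late differences were 4.52 for Sdf2l1, 4.06 for Derl3, 3.31 for Fkbp11, 3.11 for Tnfrsf12a, 2.83 for Manf, 2.77 for Creld2, 2.63 for Hyou1 and 2.47 for Pdia6. Among genes that fell in early mice they were -4.02 for Cish, -2.06 for 6430571L13Rik, -1.56 for Acvr1b, -1.17 for Mal and -0.91 for 9630013D21Rik. Among genes that rose in late mice they were -1.42 for Mid1, -1.78 for Prelp, -1.39 for Uaca, -1.25 for Tnfrsf19, -1.16 for Mmrn1, -1.05 for Atmin and -1.01 for Abcb4. Among genes that fell in late mice they were 2.41 for Myog, 2.18 for Kcne1l, 2.03 for Rab4b, 1.65 for Cthrc1, 1.57 for Nrk, 1.18 for Mymk, 0.87 for Trim2 and 0.59 for Col16a1. The sizes for Derl3, Fkbp11, Cish, Kcne1l, Nrk and Mymk are uncertain, since a group mean of each lay under the floor of 5. For 9630013D21Rik the early and late means, 3.996 and 4.91, both lay under it, so that difference is not secure.

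The same contrast separated 10 gene lists by camera, with 0 called when the correlation was estimated. Median early minus late differences were 0.86 for ER stress, 0.85 for denervation, 0.65 for extracellular matrix, 0.63 for type I interferon, 0.56 for imprinted growth, 0.41 for macrophages and 0.14 for the proteasome, and -0.87 for the clock, -0.28 for the citrate cycle and fatty acid oxidation and -0.18 for glycolysis.

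Probe sets that name several genes or none were outside the comparisons, and some of them changed: 5 of 1905 in early against control, 1 in late against control and 140 in early against late. The 1 called in late mice, which also was called in early mice, names both H2-K1 and H2-D1, with a difference of 4.16 in late and 5.39 in early mice.

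The division of 6 arrays into 3 and 3 has 10 forms, too few for a share under 0.05. For early against control the real division gave 115 genes and the highest other 0, so only the real division was as large. For late against control the values were 20 and 0, and for early against late 1119 and 27. A mixed division places any real difference within its groups, which widens their spread and lowers its count. Early and late replicate numbers were treated as pairs, and the 3 other divisions that part as many pairs gave 0 genes each.

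Higher ER stress genes in early mice stood against low values in both other groups. A single early array does not account for it, since the lowest early median was 0.997 and the highest control or late median 0.47. RNA of infiltrating plasma cells, which are rich in ER, stays open. In early 1 and 2 Ighm differed from the control mean by -4.82 and -3.76, so Ighm did not rise there. The highest difference of Ighm, Jchain and Mzb1 was 0.122. Low Ighm does not show that plasma cells were absent, since late 1 had Ighm at 7.86 and Jchain at 6.41. Jchain and Mzb1 lay under the floor of 5 in control and early arrays. Derl3, of the same fixed list, rose by 4.07 in early mice. In early 3 the highest difference was also 0.122, but Ighm, bright in controls, stood at their level. More transgene mRNA in early muscle stays open: on the H2-K1 probe set with the lowest baseline early arrays exceeded late ones by 3.29, and transgene level and age at induction cannot be told apart because every early array lay above every late array. A response of young muscle that older muscle lacks is the biological alternative and was not tested.

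Early 3 lay nearer to the controls than early 1 and 2 (correlation with the control mean over genes 0.982, against 0.934 and 0.954), and 1756 genes were called without it. An exchanged label with a control or late sample is argued against by its ER stress median of 1.27, above the 0.47 of the highest control or late array. Less transgene mRNA in early 3 was looked for on the H2-K1 probe set with the lowest baseline. The value of early 3, 11.75, lay between 11.52 in early 1 and 12.52 in early 2. It exceeded early 1 by less than the SD of the early arrays (0.52), so this explanation stays open. A milder or differently timed muscle response in that animal, and a different piece of muscle (slow fibre median -1.65), stay open and were not tested.

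Genes of the imprinted growth list, which also holds Igf1 and Igf1r, were lower in late mice, which were also older. In early mice, killed at the controls' age, 11 of 13 genes were negative as well (median -0.62; array medians -0.72, -0.20 and -0.72) and camera called the list lower (adjusted p = 0.00905), which goes against age alone. That call was lost with an estimated correlation (adjusted p = 0.443) and without early 3 (adjusted p = 0.0905), and limma's fry did not make it (adjusted p = 0.118), so age at death and transgene expression cannot be told apart for this list. The early and late values share their controls, and late mice had no controls of their own age. Drug, and genotype if the protocol holds, differ from controls in both groups; they stay open and were not tested.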

How the results depend on the processing

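The alternatives were planned before the data were examined, except the lists added under other observations, the separate test of each class I probe set, the differences counted from the floor and the replicate block for genes and sets not covered at first. None of the genes or lists run in them changed direction past its threshold. The counts of changed genes depended on the processing. For early against control (115) the count was 56 with no filter, 61 with only the 2 groups compared, 24 at an adjusted p under 0.01, 3335 with array weights and 62 with the replicate number as a block; for late against control (20) it was 13 without shared-probe sets, 12 with only the 2 groups compared, 6 at 0.01, 1037 with array weights and 5 with the replicate block. For early against late (1119) it was 584 with no filter, 1384 with every probe set kept (1794 of 17953 probe sets), 38 with only the 2 groups compared, 66 at 0.01, 501 with a 2-fold threshold and 3534 with array weights. The replicate block gave 1114, of which 865 were called without it. The named calls it ended are given with their results, and Lpl (adjusted p = 0.0521) was lost too. Cdkn1c (0.0415), Erap1 (0.0298), Psmd13 (0.0273) and Sdc4 (0.0195) passed only with it. Among the genes and sets run later that are named in the text, it ended the early against late calls of Atf3 (0.0669) and Herpud1 (0.0525). Xbp1 (0.0377) and, by camera, the STAT5 set (0.0477) passed only with it. With the block and an estimated correlation the STAT5 set did not pass by camera (adjusted p = 0.495). The calls given for Mvd, Insig1, Bmp4, Bmp6 and Smad6 stayed. The numbers do not pair early or late arrays with controls, yet the block held the control arrays as well. The values with the block therefore impose that pairing too, also in early against late. No block of early and late arrays alone is given here. Fewer genes pass at stricter thresholds by construction. The fit of only the groups compared has fewer arrays in every comparison. For early against late, where the count fell most, it also leaves out the controls, whose arrays were the most alike within a group. Which of these lowered the count was not tested, nor was the cause for the other alternatives. The array weight estimate stopped before it converged and gave early 3 a weight of 0.238 and control 2 a weight of 3.39. Leaving out each array gave 6 to 1756 genes for early against control, 5 to 59 for late against control and 143 to 2959 for early against late, the highest each time without early 3. The correlation of early and late changes (0.166) ranged from 0.113 to 0.245 in this way.

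Of the lists called by camera (18, 7 and 10 in the 3 comparisons), an estimated correlation left 0, 0 and 0, and fry called 3, 1 and 3. With no filter late against control gave 11 lists. Leaving out each array gave 14 to 20, 7 to 9 and 5 to 13 lists. Of the genes called, 111 of 115, 19 of 20 and 1000 of 1119 stayed called after median centring, and 97, 18 and 1011 after a further quantile normalization. Median centring ended the early against late calls of type I interferon (adjusted p = 0.0676) and imprinted growth (0.0512), quantile normalization those of type I interferon (0.0587) and of fast fibre genes in early against control (0.0751), and under both the complement list passed in early against control (0.0426 and 0.0469). The circadian list in early against control was lost with no filter (0.223); with the block, which does not apply there, it had 0.0845. With no filter further lists passed: interferon gamma in early (0.0241), regeneration (0.00678), oxidative phosphorylation (0.00843), the clock (0.0185) and Schwann cells (0.0146) in late against control, and regeneration (0.00526) and heat shock (0.0141) in early against late. Genes with low signal over background are the least secure: GCRMA gives dim probe sets little spread, and Derl3, called in early mice, had a control mean of 2.23.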

Other observations

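The gene sets and genes in this part were chosen after the data were seen. In all 7 sets picked by symbol were tried, all are reported here, and their p values are adjusted over the 7 within a comparison. The rise of ER genes in early mice reached beyond the fixed list. Of 81 tested genes of the secretory pathway outside that list (translocon, coat proteins, cargo receptors and N-glycosylation), 21 rose and 0 fell in early mice, with a median of 0.54 and 73 positive values (camera adjusted p = 2.6e-25; adjusted p = 0.023 with an estimated correlation). They included Arfgap3, a coat regulator of the Golgi (2.11 ± 0.16), Spcs3, of the signal peptidase (1.62 ± 0.17), Alg12 and Dpagt1, of N-glycan assembly (1.62 ± 0.20 and 1.24 ± 0.16), Copg1, of the COPI coat (1.69 ± 0.22), and Sec22b, of vesicle fusion (1.58 ± 0.21). The control mean of Alg12 lay under the floor, and counted from it the rise was 0.57. The median was 0.46, 0.63 and 0.60 over the control mean in early 1, 2 and 3. In late mice 0 passed (median -0.04). In early against late 38 were higher and 1 lower (median 0.64, camera adjusted p = 1.1e-15; adjusted p = 0.0731 with an estimated correlation). Of the 90 genes that rose in early mice, 16 were in the fixed ER list and 21 in this one.

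Among members of the fixed ER list not described above, Hspa5, the main ER chaperone (2.32 ± 0.29), Herpud1 (1.79 ± 0.26) and Syvn1, a ubiquitin ligase (2.04 ± 0.34), rose in early mice. Another 6 rose only when adjusted over the list alone: Atf3 (2.10 ± 0.49), Xbp1 (1.28 ± 0.29), Dnajc3 (1.12 ± 0.41), Ddit3 (0.84 ± 0.23), Atf6 (0.57 ± 0.18) and Edem1 (0.57 ± 0.15). The 11 that passed neither way were Atf4 (0.02), Asns (0.00093), Atf5 (-0.03), Casp12 (-1.35), Chac1 (0.34), Ddit4 (-0.26), Derl1 (0.13), Ero1a (0.02), Ppp1r15a (0.94), Sec61b (0.35) and Ssr1 (0.40). Branches of the response were not compared.

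None of the other 6 sets passed in any comparison with an estimated correlation. Fry called the BMP and SMAD set in early against control (adjusted p = 0.0153) and in early against late (adjusted p = 0.00223). It also called cholesterol synthesis in early against late (adjusted p = 0.0312). Of 17 cholesterol synthesis genes 4 were higher in early than late mice (median 0.73; adjusted p = 1.5e-05 by camera; adjusted p = 0.312 with an estimated correlation), among them Mvd (1.81 ± 0.36) and Insig1 (1.65 ± 0.37). Against controls 0 passed, and the set was lower in late mice (median -0.54, 16 of 17 negative; adjusted p = 9.3e-05 by camera; adjusted p = 0.459 with an estimated correlation) and higher in early mice (median 0.26; adjusted p = 0.038 by camera; adjusted p = 0.527 with an estimated correlation), with medians of 0.75, 0.19 and 0.01 in early 1, 2 and 3. Of 17 BMP and SMAD genes 5 were lower in early than late mice (median -0.30; adjusted p = 0.00944 by camera; adjusted p = 0.127 with an estimated correlation), including Bmp6 (-1.46 ± 0.22), Bmp4 (-1.35 ± 0.33) and the inhibitor Smad6 (-1.17 ± 0.29). In each of Mvd, Bmp4 and Smad6 1 group mean lay under the floor, from which the differences were 1.30, -1.32 and -0.88. In early against control 0 passed (median -0.30; adjusted p = 0.028 by camera; adjusted p = 0.23 with an estimated correlation).

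The STAT5 set held Cish, Ghr, Igf1, Socs2, Socs3 and Bcl6, and STAT5 activity itself was not measured. Of these 6 genes 1, Cish, fell in early mice (set median -1.06, adjusted p = 0.00396 by camera, adjusted p = 0.324 with an estimated correlation). Set medians were -1.50, -1.17 and -0.04 in early 1, 2 and 3, so early 3 had no fall. For 16 tRNA synthetases 0 passed; the set was higher by camera in early mice (median 0.18, adjusted p = 0.0117; adjusted p = 0.345 with an estimated correlation) and in late mice (median 0.27, adjusted p = 0.00459; adjusted p = 0.459 with an estimated correlation). Of 25 Hsp-named genes 0 passed in early against control (median 0.19, adjusted p = 0.0318 by camera; adjusted p = 0.438 with an estimated correlation), with medians of 0.26, 0.30 and -0.08 in early 1, 2 and 3. For 41 ribosomal protein genes 0 passed and camera made no call (median 0.08 in early against control, adjusted p = 0.104). The comparisons of these sets not given here had no camera call.

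Immunoglobulin signal differed between single animals. Ighm, the heavy chain of IgM, was 10.99, 10.51 and 11.13 in the 3 controls, 6.05, 7.12 and 10.92 in early 1, 2 and 3, and 7.86, 11.59 and 12.28 in late 1, 2 and 3. Jchain, which joins secreted antibodies, was 6.41 in late 1 and between 2.49 and 2.59 in the other 8 arrays.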
